A study of Mus musculus with 8 samples.

How the data were processed

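The series holds 8 bulk RNA-seq libraries of mouse organoids, 3-dimensional cultures of tumour epithelium, that the labels describe as hepatocellular carcinoma related to metabolic fatty liver disease. Per the labels, RNA was extracted with Trizol and column kits and libraries were made with a stranded poly(A) kit. The parental group holds 4 lines (SNU-6621, SNU-6622, SNU-6624 and SNU-6625), 1 library each. The lenvatinib group holds 2 libraries and the lenvatinib-resistant group 2 libraries, both from lines SNU-6624 and SNU-6625. The labels used here give no dose or duration of lenvatinib, and the resistant libraries carry the control label for treatment. The design text also names multi-biotics, and no library with that label was analysed here. Replicates were named by their line number.

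The deposited files list whole-number read counts per gene for 45777 genes with NCBI gene identifiers, per the file headers. The authors' tools, per the submitters' processing notes, were FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b, with build mm10. How counts were made from the alignments and which strand setting was used are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart with certainty, and near-identical gene copies (Prl2c2 and Prl2c3, H2ac18 and H2ac19, members of the Cyp2d family) may share reads. Positions come from a RefSeq table of GRCm38.p6, whose primary assembly is that of mm10, matched by gene identifier for 45679 genes.

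Total counts ran from 49.0 to 61.0 M (megacounts) per library. A count of 3 in one library, used as the floor for a value of 0, is 0.0492 to 0.0612 CPM, the count scaled to the total of its library in megacounts. This floor covers counting error only, since the reads carry no molecular identifiers. No pair of libraries held identical values. The closest pair, the lenvatinib libraries of the 2 lines, had a chi-square of 58.7 per gene.

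The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts of the 6 libraries of lines SNU-6624 and SNU-6625, with group and line as terms, TMM scaling and the tool's own filter on low counts, which kept 17038 genes. Adjusted p-values are Benjamini-Hochberg values and genes under 0.05 are called. Standard errors (SE) are the log2 fold change divided by the square root of F. The 3 groups share one estimate of the spread, with 2 residual degrees of freedom, 2.53 prior degrees of freedom and a biological coefficient of variation of 0.336. Line was a term because both lines entered each of these groups. The deviations of the libraries of one line from their group means correlated across genes at 0.504 between parental and lenvatinib, 0.288 between parental and resistant and 0.290 between lenvatinib and resistant. The p-values measure the spread between these libraries, and nothing in the labels says that libraries of one line came from separate animals.

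Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over the 36 lists with 5 or more tested members, and again with an estimated correlation and with fry. The steps were tested on simulated data for the lenvatinib comparison, with 200 changed genes among 17038 in each of 3 draws: 8% of 2-fold, 73.1% of 4-fold and 92.9% of 8-fold changes were recovered, with 14 false calls per draw. These were 16, 147 and 184 genes over the 3 draws together. False calls were thus a larger share of the calls in these draws than the threshold of 0.05. For the 2 comparisons that share the parental libraries, unchanged groups were simulated in 30 draws. Changes of 1 line were also set against those of the other line, so that no library was shared, a step added after the values were seen. Parental lines were compared by CPM scaled over all 8 libraries, without a test.

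The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took, per comparison, up to 12 largest rises and 12 largest falls among called genes that moved the same way in both lines with at least 5 CPM in the higher group, predicted genes with provisional symbols left out, up to 4 called members of each list (or the 2 largest where a called list had none), and lenvatinib targets with at least 1 CPM, and the text gives part of these. Where no gene was called in a direction, the 5 smallest p-values were taken and are given as not called. For parental lines it took 5 genes per line that stood furthest above the next line with at least 20 CPM, and the 4 highest members of each cell type list. Alternatives were a fit without line, all 8 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(CPM + 1) and log2(CPM + 0.1), other scaling, other filters, genes above 1% of counts left out, a fold minimum of 2 and each library left out in turn. A fit to only the 4 libraries of the groups compared was added after seeing the data. Figures and checks used Python with numpy and matplotlib.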

Results

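Gene expression was measured in 8 organoid libraries from 4 mouse tumour lines. Each of the 4 lines had 1 untreated parental library. Lines SNU-6624 and SNU-6625 each also had 1 library after lenvatinib, an inhibitor of VEGF, FGF and PDGF receptors, KIT and RET, and 1 library of a lenvatinib-resistant culture. Total counts were 52.3, 58.5, 60.4 and 49.0 M (megacounts) in parental SNU-6621, SNU-6622, SNU-6624 and SNU-6625, 56.6 and 54.4 M in the lenvatinib libraries of SNU-6624 and SNU-6625, and 50.5 and 61.0 M in the resistant libraries of the same lines. Between 19426 and 20867 genes had counts above 0. Ribosomal RNA genes held 0.0942% to 0.1103% of counts in the parental libraries and 0.0411% to 0.0533% in the lenvatinib and resistant libraries. The labels used here name no batch. A difference in preparation between the parental and all other libraries would not give changes found in the lenvatinib libraries alone, such as that of Hnf4a (5497 and 7296 counts in parental SNU-6624 and SNU-6625, 5526 and 7367 in resistant, 316 and 594 in lenvatinib libraries). Hmox1 was highest in the lenvatinib libraries, with 1829 and 1082, 1930 and 3615, and 44493 and 20520 counts in the same order. It was also higher in resistant than in parental SNU-6625, so its rise was not confined to the lenvatinib libraries. For changes that the lenvatinib and resistant libraries share against parental, a difference in preparation cannot be told apart from the groups.

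The first question, from the series title, is what the parental organoids express. The labels describe hepatocellular carcinoma organoids. The 4 lines carried high levels of bile duct, progenitor and some intestinal genes. The keratin genes Krt19 and Krt7 had 2986 ± 234 CPM and 2377 ± 292 CPM (mean ± SD, n = 4 lines), the stem cell surface protein gene Prom1 had 1460.4 ± 282 CPM, and the epithelial adhesion gene Epcam had 464 ± 105 CPM. Of 22 genes of the biliary and progenitor list, 14 had at least 10 CPM in every parental line. Of 28 mature hepatocyte genes, 3 did: Hnf4a, a transcription factor of liver and gut epithelium, at 115 ± 29.5 CPM, Cebpa at 44.5 ± 42.4 CPM and the urea cycle gene Ass1 at 32.8 ± 24.5 CPM. Of 26 intestinal epithelium genes, a list chosen after its values were seen, 10 did, among them Lgals4 at 1209.7 ± 473 CPM and Cdh17 at 639 ± 280.1 CPM, and the gut transcription factor gene Cdx2 had a mean of 128 CPM. These levels alone do not settle the tissue of origin. Albumin (Alb) had 0 counts in all 8 libraries, against a floor of 3 counts per library, and the transthyretin gene Ttr had 0.507 ± 0.637 CPM. Of 19 fetal liver and hepatocellular carcinoma genes, 5 reached 10 CPM in every parental line, among them Scd2 at 2281 ± 966 CPM, Ly6d at 474 ± 302 CPM and Golm1 at 253 ± 62.1 CPM. The fetal liver gene Afp had 0.00875 ± 0.0175 CPM.

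**Figure D1:**
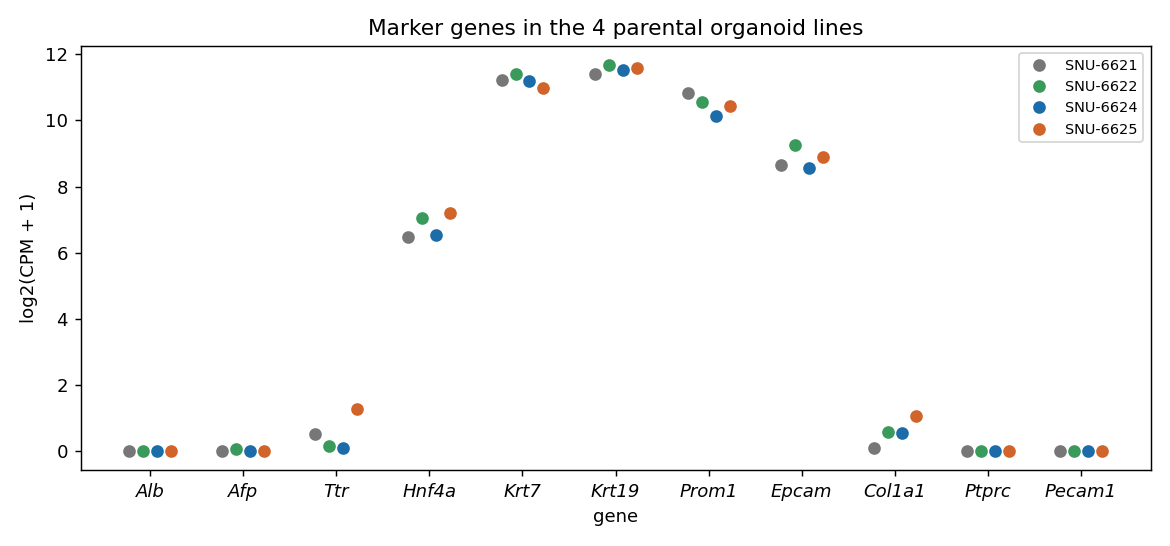
Marker genes in the parental lines: each point is the log2(CPM + 1) of 1 library, coloured by line, with genes along the horizontal axis. Krt7 and Krt19 are high in each of the 4 lines and Alb is at 0 in each.

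Most genes of other cell types were low. At most 3 counts in each of the 8 libraries were found for 11 of 16 stellate cell and fibroblast genes, 11 of 16 macrophage genes, 6 of 14 endothelial genes, 11 of 17 lymphocyte genes and 7 of 7 red blood cell genes. Among the exceptions were the endothelial gene Egfl7, at 7.03 ± 2.52 CPM, and Lrat and Esam, at 22.9 and 11.4 CPM in SNU-6621. None of 16 stellate cell and fibroblast genes reached 10 CPM in every parental line, nor did any of 14 endothelial, 17 lymphocyte or 7 red blood cell genes. One of 16 macrophage genes did, the lysosomal gene Cd68 at 33.8 ± 16.7 CPM, while the leukocyte gene Ptprc had 0 CPM in each parental line. Among the receptors that lenvatinib inhibits, Kdr, Kit and Pdgfrb had 0 CPM in each parental line, Ret had 9.35 ± 4.46 CPM and Fgfr3 5.78 ± 3.77 CPM. Flt1, Fgfr1 and Fgfr2 had 38.4, 17.8 and 31.6 CPM in SNU-6621, and at most 0.210, 0.228 and 0.352 CPM in the other lines.

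The lines differed in sets of genes. SNU-6621 stood furthest from the rest, with Spearman correlations across genes of 0.926 to 0.936 to the other lines, against 0.971 to 0.976 among those. Its most distinct genes were the matrix gene Tnc at 459.6 CPM, Adamts1 at 389 CPM, Akap12 at 159 CPM, Mill1 at 161 CPM and the hair keratin gene Krt84 at 1752 CPM. In SNU-6622 the 5 most distinct genes, Ifit3 (174 CPM), Ifit3b (96.4 CPM), Sp100 (108 CPM), Trim30a (121 CPM) and Ifi44 (299.6 CPM), are all known to be induced by interferon. SNU-6624 was highest in the Wnt antagonist gene Notum at 81.5 CPM, in Fbln2 at 79.4 CPM, Klk10 at 60.5 CPM, Sgcd at 33.4 CPM and Akr1c14 at 21.4 CPM. SNU-6625 was highest in the carboxylesterase gene Ces2a at 181 CPM, the antimicrobial lectin gene Reg3b at 46.8 CPM, Agr2 at 33.0 CPM, Smoc1 at 23.7 CPM and Adgrl3 at 22.3 CPM. No line had a second parental library, so differences among the parental libraries were not tested.

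The next question is what lenvatinib changed. Lenvatinib-treated organoids had more transcript of the stress gene Hmox1, which encodes heme oxygenase, than the parental organoids of the same 2 lines. They had less of the cell division gene Foxm1, the sterol synthesis gene Hmgcs1 and the epithelial genes Hnf4a and Krt19. Hmox1 (gene 15368, chromosome 8, 75093618 to 75100593, mm10) went from 26.2 ± 6.22 to 555.6 ± 297 CPM (mean ± SD, n = 2 lines each), a log2 fold change of 4.38 (SE 0.57, edgeR adjusted p = 0.0398). Hnf4a (gene 15378, chromosome 2, 163506811 to 163572907) fell by 3.97 on the log2 scale (SE 0.21, edgeR adjusted p = 0.0275), from 119.5 ± 38.9 to 7.72 ± 3.23 CPM. The mitotic transcription factor gene Foxm1 fell by 6.07 on the log2 scale (SE 0.81) and the intestinal and liver stem cell gene Lgr5 by 5.48 (SE 0.51). In total 985 of 17038 genes were called, of which 289 rose and 696 fell, each of them in the same direction in both lines.

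**Figure D2:**
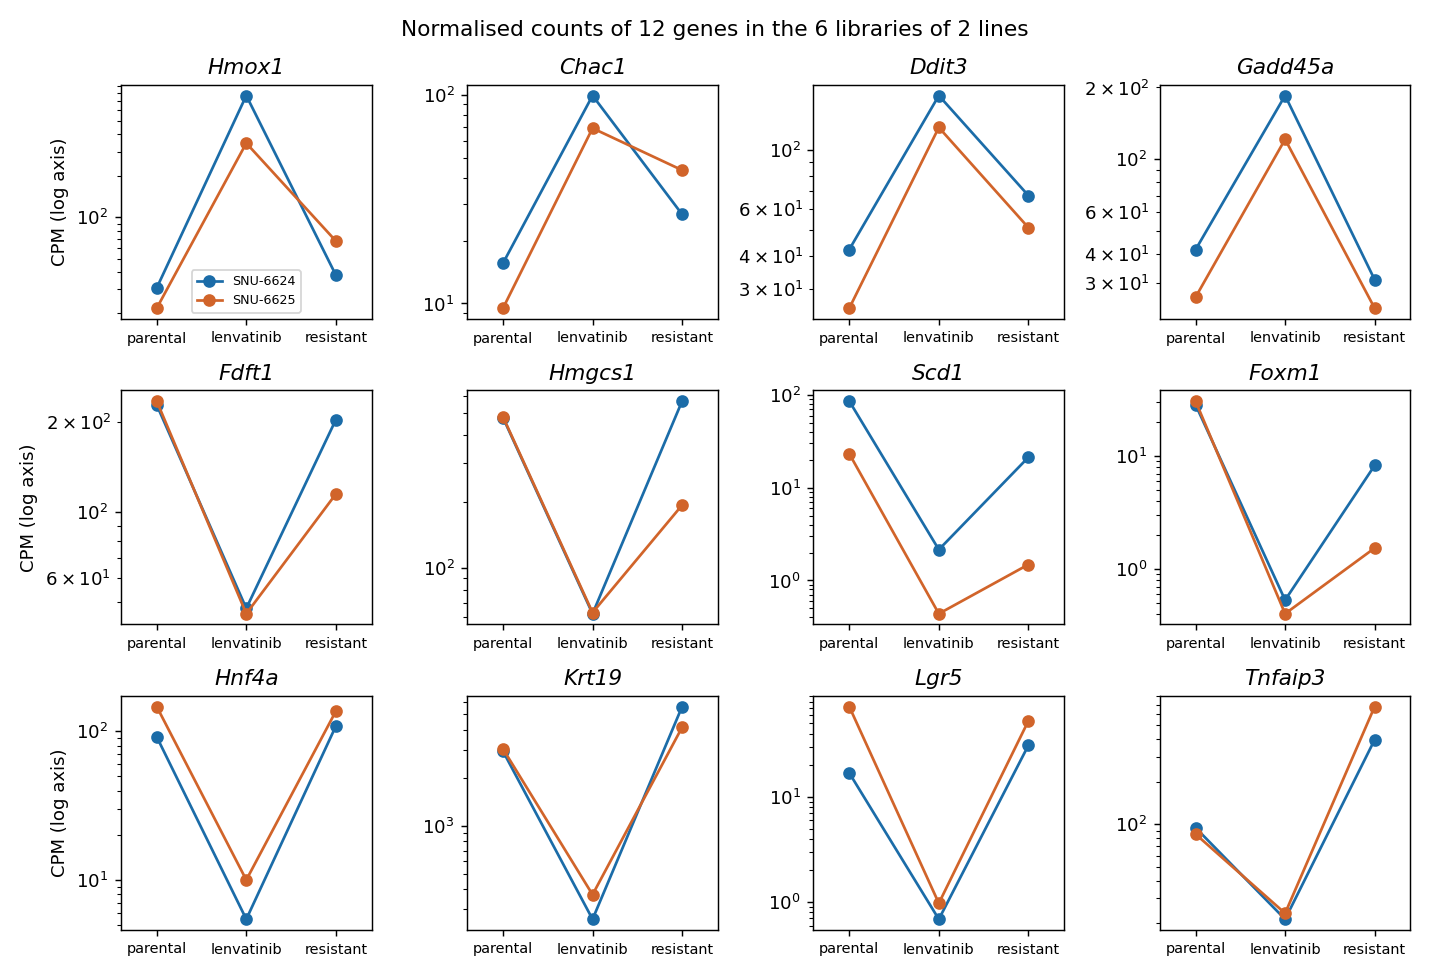
Normalised counts of selected genes: each point is the CPM of 1 library on a log axis, with the groups along the horizontal axis and 1 line per organoid line. Hmox1, Chac1, Ddit3 and Gadd45a are highest, and the other genes lowest, in the lenvatinib libraries of both lines.

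The largest rises after Hmox1 were in Arfgef3 (3.52, SE 0.37), the heat shock gene Hsph1 (3.48, SE 0.52), Osbp2 (3.23), Trnp1 (3.15), Zmat1 (3.02), Ces1f (2.92) and Chac1 (2.75), which encodes a glutathione-degrading enzyme; these values are log2 fold changes. The integrated stress response list rose as a group, with 7 of 25 members called up, 0 called down and 18 not called (14 up when adjusted over the list alone). Its members included Chac1, the transcription factor gene Ddit3 (2.09, SE 0.17), the serine synthesis gene Phgdh (1.71, SE 0.16) and the asparagine synthetase gene Asns (1.68, SE 0.28). NRF2 targets, the antioxidant genes, also rose as a group, with 2 of 20 called, Hmox1 and Taldo1 (1.45, SE 0.23), and 10 when adjusted over the list alone. The lysosome and autophagy list rose with 0 of 22 members called (4 up and 1 down adjusted over the list alone). For each of these 3 lists the adjusted p = 0.761 with an estimated correlation. The growth arrest gene Gadd45a rose by 2.18 (SE 0.15).

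Cell cycle lists fell. The G2/M list had a median log2 fold change of -4.16, with 3 of 30 members called down (14 adjusted over the list alone), among them Foxm1, Kif23 (-3.43) and Birc5 (-2.85). The G1/S list had a median of -1.60, with 2 of 30 called down (2 adjusted over the list alone), the transcription factor gene E2f2 (-5.62) and the thymidine kinase gene Tk1 (-4.73). Cholesterol synthesis fell with a median of -1.78 and 7 of 23 called down (20 adjusted over the list alone), including Hmgcs1 (-2.94), Stard4 (-2.34) and Fdft1 (-2.32). Fatty acid synthesis fell, with 4 of 20 called down and 1 called up (12 down and 2 up adjusted over the list alone), led by the desaturase gene Scd1 (-5.60), Elovl6 (-3.01) and Srebf1 (-1.29). The adjusted p = 0.761 with an estimated correlation for each of these 4 lists.

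Epithelial and inflammatory genes fell too. The biliary and progenitor list had 4 of 22 members called down (7 adjusted over the list alone): Muc1 (-3.62), Krt19 (-3.25), Tspan8 (-3.12) and Spp1 (-3.10). The stem and organoid list had 3 of 12 called down (6 adjusted over the list alone): Lgr5, Ly6a (-2.83) and the Wnt target gene Axin2 (-1.46). The cytochrome P450 and drug and bile acid transport list had 3 of 12 called down (3 adjusted over the list alone). These were the enzyme genes Cyp2d9 (-5.87), Sult1a1 (-2.52) and Cyp3a13 (-1.92). NF-kB and acute phase genes had 6 of 18 called down (8 adjusted over the list alone), including the chemokine genes Cxcl5 (-2.47) and Cxcl2 (-2.46) and the NF-kB inhibitor gene Tnfaip3 (-2.02). Interferon response genes had 5 of 25 called down (8 adjusted over the list alone), including Oas2 (-3.71) and Irf7 (-1.29). Mesenchymal, epithelial junction, hypoxia and mitochondrially encoded lists also passed camera downward, with 1 of 13, 1 of 22, 0 of 26 and 1 of 13 members called and 4, 1, 6 and 4 down adjusted over the list alone. For each of the 9 lists of this paragraph the adjusted p = 0.761 with an estimated correlation.

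Single genes that fell most included Flacc1, with 0 counts in both lenvatinib libraries and at least 117-fold lower than in parental organoids against a floor of 3 counts per library, the complement gene C4bp (-7.57), Otop3 (-7.48), Agr2 (-7.25), Htra3 (-6.93) and the vitamin A receptor gene Stra6 (-6.63). In lenvatinib SNU-6624 and SNU-6625, C4bp had 0 and 18 counts, Otop3 16 and 0, Agr2 0 and 17 and Htra3 3 and 9. The sizes of these 4 falls are therefore uncertain. In parental SNU-6624 and SNU-6625, Agr2 had 109 and 1634 counts and Htra3 90 and 1982, so both rest mostly on SNU-6625. Of the lenvatinib targets with at least 1 CPM, Ret fell by 4.69 on the log2 scale (SE 0.63), Fgfr3 had -1.38 (SE 0.58) and Flt4 1.83 (SE 0.54), the latter pair not called. Without scaling beyond library size, 427 genes rose and 556 fell, so that 43.4% of calls were rises, against 29.3%. For lenvatinib against parental, the count of edgeR calls depended on single libraries. It fell when a parental or a lenvatinib library was left out and rose when a resistant library was left out. The resistant libraries take no part in this comparison, but the difference between them enters the shared estimate of the spread.

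The third question is how resistant organoids differ from the parental ones. No gene was called by edgeR, whose smallest adjusted p was 0.247, although 2715 of 17038 genes had an unadjusted p under 0.05, where chance gives 852. DESeq2 called 1072 genes, limma-voom 0 and limma-trend 0. The resistant libraries of the 2 lines differed from each other: the cell division gene Mki67 had 1970 counts in resistant SNU-6624 and 17 in resistant SNU-6625, against 12767 and 11437 in the parental libraries. The fold changes of the 2 lines correlated across genes at 0.383, against 0.815 for lenvatinib. Genes are not independent replicates, so these values describe the libraries alone.

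**Figure D3:**
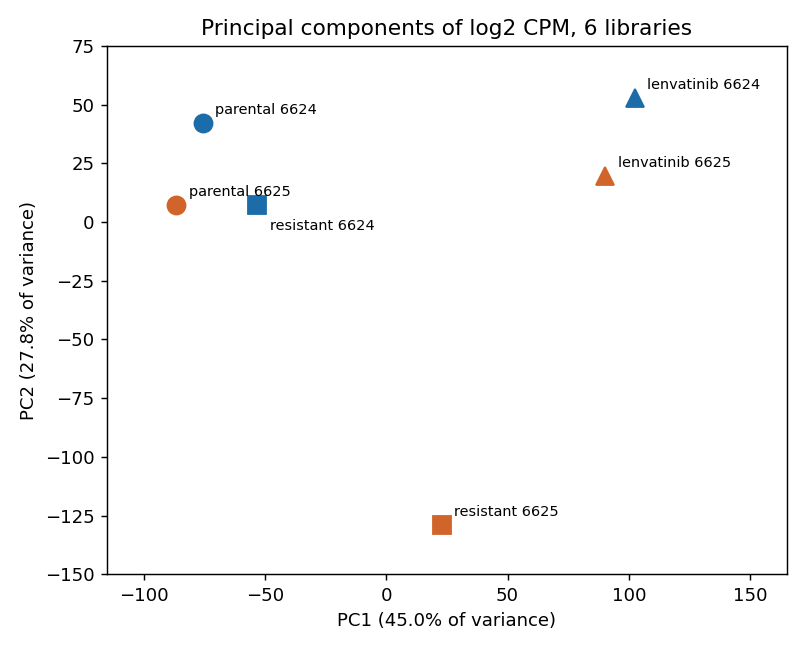
Principal components of log2 CPM: each point is 1 of 6 libraries, with PC1 (45.0% of variance) on the horizontal and PC2 (27.8%) on the vertical axis. The lenvatinib libraries lie at 102 and 90.2 on PC1, and resistant SNU-6625 lies at -129 on PC2.

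Among genes with the smallest p-values, none called (edgeR adjusted p = 0.247 for each), the cornified envelope gene Ivl had a log2 fold change of 2.73 (SE 0.21), with 2845 and 2728 counts in parental and 17851 and 17388 in resistant libraries. Gml had 5.67 (SE 0.53), Rnd1 2.29 (SE 0.20), Entpd3 1.78 (SE 0.16) and Utp14b 1.60 (SE 0.16). On the other side were the circadian transcription factor gene Dbp at -4.12 (SE 0.27), Reg3g at -6.81 (SE 0.59), Aldh1l2 at -2.75 (SE 0.19), Ctnnal1 at -1.85 (SE 0.16) and Acss2 at -1.63 (SE 0.18). Reg3g had 7 and 1173 counts in parental SNU-6624 and SNU-6625 and 0 and 11 in the resistant libraries. Its value therefore rests largely on SNU-6625.

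By camera, 14 of 36 lists differed. The p53 target list rose with a median log2 fold change of 0.95, 0 of 20 members called and 10 up when adjusted over the list alone, with Plk2 at 2.07 and Fas at 1.60. The value of Fas came from SNU-6625, with 49 counts in its parental and 371 in its resistant library, against 63 and 64 in SNU-6624. NF-kB and acute phase genes (median 1.36, 0 of 18 called, 6 up and 1 down adjusted over the list alone) and biliary and progenitor genes (median 0.50, 0 of 22 called, 6 up adjusted over the list alone) rose, and both contain Lcn2 (4.54), an acute phase gene. Another acute phase gene, Saa1, had -3.64 (edgeR adjusted p = 0.414, not called), with 2910 and 2474 counts in parental and 538 and 4 in resistant libraries. Epithelial junction (0.49), ERK output (0.40), Notch (0.60) and integrated stress response (0.27) lists passed camera upward as well, the last with medians of -0.03 in SNU-6624 and 0.55 in SNU-6625, with 0 members called in each and 0, 0, 1 and 3 members up, and 0, 0, 1 and 0 down, adjusted over the list alone. The G2/M list fell with a median of -3.40, 0 of 30 called and 1 down adjusted over the list alone, at -2.02 in SNU-6624 and -6.38 in SNU-6625. The G1/S (-1.21), cholesterol (-0.62), fatty acid synthesis (-0.73), hypoxia (-0.33), mitochondrially encoded (-0.45) and ribosomal protein (-0.27) lists passed camera downward, with 2 members down in fatty acid synthesis and 0 in the others adjusted over the list alone. Of the lists that passed upward, medians in SNU-6624 and SNU-6625 were 0.52 and 1.26 for p53 targets, 0.72 and 1.75 for NF-kB and acute phase genes, 0.20 and 0.62 for biliary and progenitor genes, 0.31 and 0.72 for epithelial junctions, 0.15 and 0.64 for ERK output and 0.30 and 0.88 for Notch. Most of the downward differences lay in a single line: in SNU-6624 and SNU-6625 the medians were -0.15 and -2.83 for G1/S, -0.07 and -1.27 for cholesterol, -0.15 and -1.35 for fatty acid synthesis, -0.04 and -0.54 for ribosomal proteins, -0.74 and -0.07 for mitochondrially encoded genes and -0.21 and -0.48 for hypoxia. The adjusted p = 0.834 with an estimated correlation for ribosomal proteins and 0.819 for each of the other 13 lists. Of the lenvatinib targets, Ret had -1.51 (SE 0.56), Fgfr3 -1.27 (SE 0.59) and Flt4 1.26 (SE 0.52), none called.

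For resistant against parental, the count of edgeR calls was 5819 without resistant SNU-6624 and 580 without resistant SNU-6625. It was 0 without parental SNU-6624 (1501 unadjusted), parental SNU-6625 (660 unadjusted), lenvatinib SNU-6624 (1729 unadjusted) or lenvatinib SNU-6625 (1729 unadjusted). The number of lists called was 6 without parental SNU-6625 and 5 without resistant SNU-6625.

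The fourth question is how resistant organoids differ from lenvatinib-treated ones. Resistant organoids had more transcript of the epithelial genes Krt19 and Hnf4a, the stem cell gene Lgr5 and the chemokine gene Cxcl5. They had less of the stress genes Hmox1 and Ddit3. The resistant libraries carry the control label for treatment, so resistance cannot be told apart from the difference in treatment. Hnf4a had 5497 and 7296 counts in parental and 5526 and 7367 in resistant SNU-6624 and SNU-6625. For Lgr5 they were 1010 and 3583 against 1573 and 2843. Krt19 (175697 and 150911 against 285064 and 223933) and Cxcl5 (798 and 1307 against 2354 and 14071) had higher counts in both resistant libraries. Krt19 (gene 16669, chromosome 11, 100140810 to 100145926) went from 315 ± 78.3 to 4882 ± 1022 CPM (mean ± SD, n = 2 lines each), a log2 fold change of 3.96 (SE 0.40, edgeR adjusted p = 0.0304), Hnf4a 4.05 (SE 0.21, edgeR adjusted p = 0.0174) and Lgr5 5.63 (SE 0.51, edgeR adjusted p = 0.0272), while Hmox1 fell by 3.31 (SE 0.55, edgeR adjusted p = 0.0470). Of 17038 genes 1061 were called, of which 706 rose and 355 fell, each in the same direction in both lines.

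**Figure D4:**
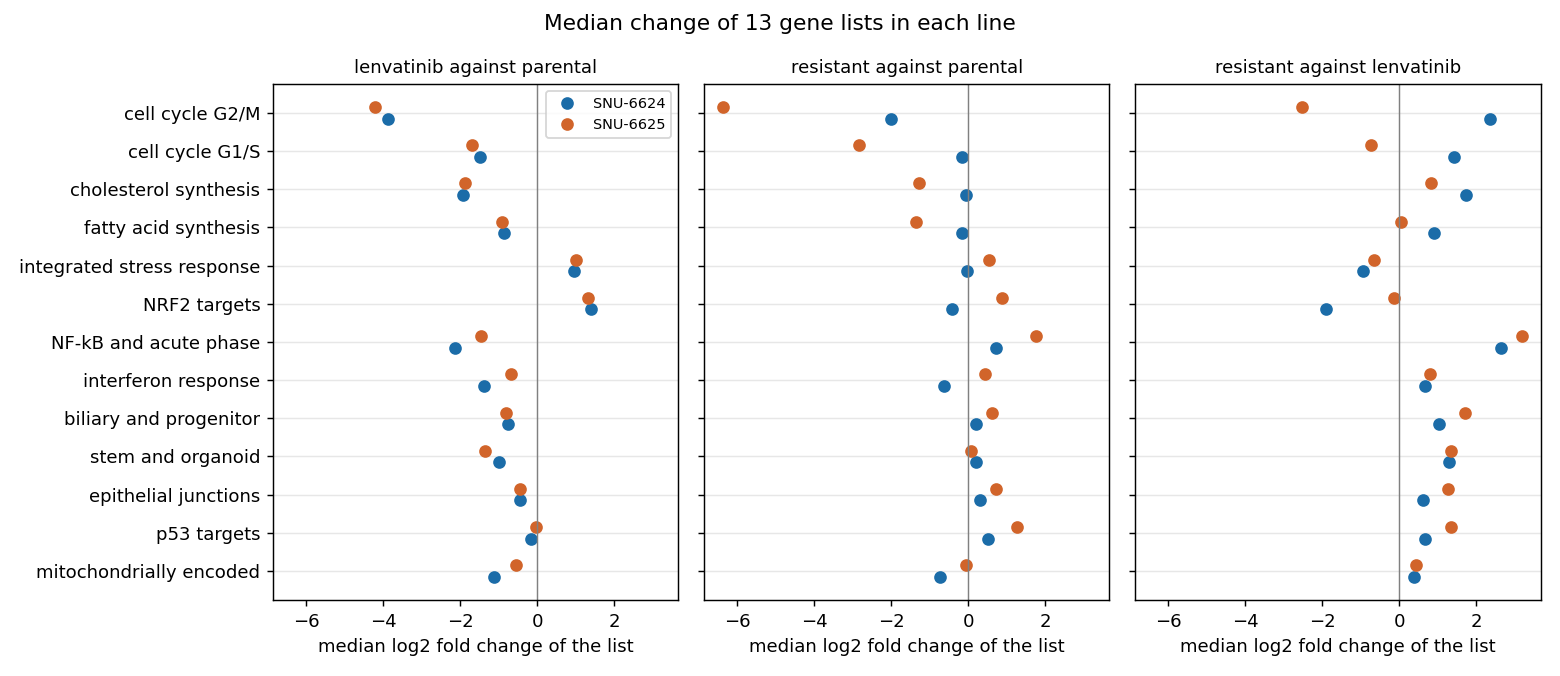
Median log2 fold change of gene lists, 1 panel per comparison: each point is the median of 1 list in 1 line, and the vertical line marks 0. The G2/M list lies at 2.35 in SNU-6624 and -2.54 in SNU-6625 for resistant against lenvatinib, while NF-kB and acute phase genes lie at 2.63 and 3.18.

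The largest rises included the mucin gene Muc4 (6.81, SE 0.29), the prolactin family genes Prl2c3 (7.58) and Prl2c2 (6.55), which may share reads, the cornified envelope gene Lor (6.91), the keratin gene Krt15 (6.21), the water channel gene Aqp3 (6.16), Duoxa2 (7.03), Fut9 (6.51) and Anxa13 (6.01). The macrophage receptor gene Mrc1 had 0 counts in both lenvatinib libraries and 18 and 786 in resistant SNU-6624 and SNU-6625, so that its rise rests largely on SNU-6625. The macrophage gene Csf1r rose by 4.02 (SE 0.64) on 3 and 4 against 36 and 73 counts. The largest falls were in Zmat1 (-3.66), Ces1f (-3.58), Osbp2 (-3.53), Exoc3l (-3.40), Slc27a3 (-3.35), Hmox1, Arfgef3 (-3.26) and the clock gene Ciart (-3.22).

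NF-kB and acute phase genes rose as a group, with 8 of 18 members called up (14 adjusted over the list alone), including Cxcl5 (5.02), Tnfaip3 (4.55), Cxcl2 (4.33) and Ccl20 (3.96). Their median was 3.24, or 2.79 with genes at 0 set to their bound. The biliary and progenitor list had 7 of 22 called up (14 adjusted over the list alone), with Spp1 (5.48), Tspan8 (3.43) and Krt7 (2.38) beside Krt19. The stem and organoid list had 5 of 12 called up (6 adjusted over the list alone), with Sox4 (2.31) and Ly6a (2.18), and Wnt targets had 3 of 12 (6 adjusted over the list alone), with Axin2 (1.36) and the cyclin gene Ccnd1 (1.59). The adjusted p = 0.656 with an estimated correlation for each of these 4 lists.

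Epithelial junction genes rose with 5 of 22 called (15 adjusted over the list alone), with Cldn2 (2.53) and Krt8 (2.48). Cholesterol synthesis rose with 4 of 23 called (15 adjusted over the list alone), with Fdft1 (1.74) and Msmo1 (1.41), and p53 targets with 2 of 20 (14 adjusted over the list alone), Eda2r (1.89) and Tnfrsf10b (1.20). Mesenchymal (3 of 13 called), interferon (1 of 25) and apoptosis (4 of 20) lists rose, with Thbs1 (2.62), Oas2 (2.67) and Birc3 (3.13) and with 3, 4 and 11 members up and 0, 1 and 2 down adjusted over the list alone. The integrated stress response fell with 5 of 25 called (9 down and 1 up adjusted over the list alone), including Trib3 (-2.96), Pycr1 (-1.76) and Ddit3 (-1.25), and NRF2 targets fell with 1 of 20 called, Hmox1 (0 adjusted over the list alone), and with medians of -1.90 in SNU-6624 and -0.14 in SNU-6625. The adjusted p = 0.815 with an estimated correlation for each of these 8 lists. Lipid droplet genes rose (0 of 11 called, 6 up adjusted over the list alone). The cytochrome P450 and drug and bile acid transport list rose too, with 1 of 12 called, the enzyme gene Cyp3a13 at 3.04. In that list 5 were up and 1 down adjusted over the list alone. The adjusted p = 0.656 with an estimated correlation for both lists. The G2/M list did not pass camera, whose direction was down while its median was 0.79 and its mean 0.96.

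For resistant against lenvatinib scaled by library size alone, the median of all genes moved from 0.02 to -0.14, and 596 genes rose and 663 fell, 47.3% rises against 66.5%. The count of edgeR calls was 90 without parental SNU-6624, 118 without parental SNU-6625, 0 without lenvatinib SNU-6624 (2435 unadjusted), 0 without lenvatinib SNU-6625 (2308 unadjusted), 6286 without resistant SNU-6624 and 5867 without resistant SNU-6625.

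The lenvatinib and resistant changes against the same parental libraries shared 0 edgeR calls, because none was made for resistant organoids, and independent lists would share 0. By DESeq2 99 genes rose in both, where independent lists would share 38.7, and 350 fell in both, where they would share 79.2. Their fold changes correlated across genes at 0.4989, and unchanged groups simulated against the same parental libraries gave 0.5004 ± 0.0124 (SD, 30 draws). The covariance was 1.11 against a simulated 0.212 ± 0.00841. Among genes with at least 5 CPM in 2 libraries it was 0.417, for which the simulation was not repeated. The direction was the same for 63.3% of genes, against 66.6% in the simulation. The simulation contains the shared controls, and the covariance beyond it was 0.897. It does not contain a difference in preparation between the parental and all other libraries. Such a difference cannot be told apart from changes shared by lenvatinib and resistance, here or in the comparison across lines that follows. In a comparison added after the values were seen, lenvatinib in 1 line was set against resistance in the other, each from its own parental library. The covariance of log2 CPM changes was 0.932 for lenvatinib in SNU-6624 with resistant SNU-6625 and 0.275 for lenvatinib in SNU-6625 with resistant SNU-6624, against 0.442 within SNU-6624 and 1.19 within SNU-6625, where the parental library is shared. These were not simulated. Part of the excess in shared DESeq2 calls may come from the shared controls, since 2 parental libraries are too few to split for that test.

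Between lines, the last question, SNU-6625 differed from SNU-6624 in 2 called genes over the 3 conditions (line SNU-6625 against line SNU-6624). DESeq2 called 577, limma-voom 8 and limma-trend 10. The kinase gene Tnk1 (gene 83813, chromosome 11, 69850563 to 69858730) had 71.5 ± 22.9 CPM in SNU-6625 and 0.0308 ± 0.0296 CPM in SNU-6624 (mean ± SD, n = 3, edgeR adjusted p = 0.0286), and the predicted gene Gm42048 (gene 105246824), chosen for mention after its values were seen, had 151 ± 164 and 0.164 ± 0.220 CPM (edgeR adjusted p = 0.0177). Both were higher in 3 of 3 conditions. The Y-linked gene Ddx3y had 0 counts in each SNU-6625 library and was at least 1960-fold lower than in SNU-6624 against a floor of 3 counts per library, though not called (edgeR adjusted p = 0.0779). Not called either were the ion channel gene Trpv4 (-5.01, SE 0.23), Fbln2 (-2.63), Klk10 (-2.21) and Tgm1 (-2.43). By camera 13 of 36 lists differed, among them antigen presentation (median 0.72, 5 of 13 up adjusted over the list alone) and efflux pumps (0.75, 4 of 12 up adjusted over the list alone) upward and G2/M (-0.98) and G1/S (-0.88, 0 of 30 adjusted over the list alone for both) downward. The upward differences were largest in the resistant libraries. For G2/M genes SNU-6625 was lower in the resistant pair alone, and for G1/S genes the gap was small outside that pair. The mean log2 CPM of antigen presentation genes in SNU-6625 and SNU-6624 was 4.105 and 3.76 in parental, 4.16 and 3.79 in lenvatinib and 5.26 and 3.81 in resistant libraries, and that of efflux pumps was 5.62 and 5.22, 5.11 and 4.51, and 6.24 and 4.90. In the same order, that of G2/M genes was 5.39 and 5.24, 1.11 and 0.85, and -1.17 and 3.28, and that of G1/S genes was 4.45 and 4.37, 2.47 and 2.54, and 1.68 and 4.28. The adjusted p = 0.818 with an estimated correlation for each of these 4 lists. The count of genes was 567 without resistant SNU-6624, 474 without resistant SNU-6625, 1 without lenvatinib SNU-6624, and 0 without parental SNU-6624 (943 unadjusted), parental SNU-6625 (944 unadjusted) or lenvatinib SNU-6625 (1021 unadjusted). The number of lists called was 6 without resistant SNU-6624 and 5 without resistant SNU-6625.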

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

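The tests of the resistant SNU-6625 library, of the Y-linked genes and of the share of chromosome 2 genes were chosen only after these results were seen.

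Of 53 parental genes examined, 27 had 1 line far from the other 3. The rule flags about 1 in 20 sets of normally distributed values, a rate that skewed CPM can exceed. Of the 27 genes, 19 were named for standing highest in 1 line, which builds the gap in. These 19 were Tnc (459.6 CPM), Adamts1 (389.4), Mill1 (160.5), Akap12 (158.6) and Krt84 (1752) in SNU-6621, Ifit3 (173.5), Ifit3b (96.41), Sp100 (107.5), Trim30a (120.7) and Ifi44 (299.6) in SNU-6622, Akr1c14 (21.36), Fbln2 (79.43), Notum (81.55) and Klk10 (60.54) in SNU-6624, and Reg3b (46.81), Smoc1 (23.68), Ces2a (181.3), Agr2 (32.96) and Adgrl3 (22.29) in SNU-6625. The others were Ass1 (69.34), Esam (11.38), Lck (3.232), Flt1 (38.43), Flt4 (12.74), Fgfr1 (17.82) and Fgfr2 (31.56) in SNU-6621 and Cd68 (58.67) in SNU-6622.

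The medians of the 2 lines had opposite signs in 24 of 108 pairs of list and comparison: 5 of 36 for lenvatinib against parental, 11 for resistant against parental and 8 for resistant against lenvatinib. These differences were not tested. The pairs that passed camera, or had both medians at least 0.5 from 0, were 3. For resistant against lenvatinib the median log2 fold change of G2/M genes was 2.35 in SNU-6624 and -2.54 in SNU-6625, and that of G1/S genes 1.43 and -0.75. For resistant against parental the integrated stress response had -0.0312 and 0.547.

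The first pattern is the resistant SNU-6625 library, which lay at -129 on the second principal component. Its depth, 61.0 M counts against a median of 54.4 M for the other 5 libraries, and the 6.98% of counts in its 10 most counted genes, against a median of 8.69%, argue against low depth and against a few genes taking the counts. A library from another line is also argued against, but only on a bound set after a first one had left the question undecided. Of 43 genes that separate the lines 4-fold, only 35 stood on the SNU-6625 side (81.4%), which led to the 16-fold bound. Of the genes that separate them at least 16-fold in parental and lenvatinib libraries, 10 of 10 stood on that side. Among these, Kdm5d, Uty, Ddx3y and Eif2s3y all lie on the Y chromosome, so they are not separate markers. The library may hold few dividing cells, since its G2/M median against parental was -6.38, further down than any other list (next -2.83). Low G2/M values alone do not place a library there on the second component. The lenvatinib libraries of SNU-6624 and SNU-6625 had G2/M medians of -3.88 and -4.21 and lay at 52.8 and 19.6 on it. Whether the low G2/M level belongs to resistance or to 1 culture stays open, with a single library.

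The second pattern is chromosome 2 in parental SNU-6625, whose 881 genes of at least 5 CPM on average had a median 0.25 higher on the log2 scale than in parental SNU-6622 and SNU-6624, relative to other autosomes, which lay between -0.03 and 0.04. A few strong genes are argued against by the 85.5% of genes above the median of other autosomes, and GC content, length and expression level by 0 of 10000 matched gene sets reaching the shift (largest 0.03). A gain of chromosome 2 in part of the cells is a candidate explanation, as each of 5 segments was shifted, by 0.15 to 0.38, with the largest shift in the first segment and the lowest in the last. The shift was 0.11 in resistant SNU-6625, where other autosomes lay between -0.07 and 0.08, and 0.09 in lenvatinib SNU-6625, where they lay between -0.09 and 0.10, so it did not stand out in the latter. DNA was not analysed here, so copy number itself was not measured.

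The third pattern is the low level of Y-linked genes in parental SNU-6622, where Ddx3y, Eif2s3y, Kdm5d and Uty together had a median of 10.1% of their level in SNU-6624. Cells of SNU-6621 in that culture are argued against by 108 genes of at least 20 CPM in SNU-6621 that stayed under 1/3 of the level such a share would bring. For cells of SNU-6624 only 2 of 7641 genes did, too few to exclude them. Most of these genes could not have, since only 249 of 17542 genes differed over 4-fold in CPM + 1 between parental SNU-6622 and SNU-6624. The test therefore says little, and a mixture with SNU-6624 cannot be told apart from Y loss. Loss of the Y chromosome in part of the cells could give the near-equal ratios to SNU-6624, whose largest was 1.23 times the smallest. Against SNU-6621 the ratios were less even, from 16.2% for Kdm5d to 26.7% for Eif2s3y.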

How the results depend on the processing

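Of 247 log2 fold changes of named genes, 162 of them called, 0 called values changed sign in 18 alternatives. Among values not called in either, 9 changed sign, such as Flt4 in lenvatinib against parental (-0.55 with no replicate block and all 8 libraries). The main calls were 985 for lenvatinib against parental, 0 for resistant against parental, 1061 for resistant against lenvatinib and 2 for line SNU-6625 against line SNU-6624. Without the replicate block (line) they were 1053, 0 and 1119, and the list calls 16, 12 and 12, so that no count moved by over 1.5 times, while 48 values of named genes were no longer called, 1 became called and 162 kept their side of the threshold. Without a count filter 111 were no longer called and 136 kept their side. The cause of the larger moves below was not tested. Settings with fewer libraries have fewer degrees of freedom, which alone would lower a count and does not explain the rises. With 1 resistant library left out, the model fits the other exactly. The spread then comes from the parental and lenvatinib libraries alone, while in the main fit the difference between the resistant libraries also enters it. With no replicate block and all 8 libraries, 2279 genes were called for lenvatinib and 3 for resistant against parental. DESeq2 called 3605, 1072, 3487 and 577 in the order above. limma-voom called 1697 for lenvatinib and 8 for lines, limma-trend on log2(CPM + 1) 1505 and 10, and on log2(CPM + 0.1) 1801 and 12, with 1682 for resistant against lenvatinib. Without a count filter the counts were 174 for lenvatinib and 324 for resistant against lenvatinib. With at least 5 CPM in 2 libraries they were 1660 for resistant against lenvatinib and 8 for lines. The fit to only the 4 libraries compared, chosen after seeing the data, called 7942 for lenvatinib and 234 for resistant against lenvatinib.

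With a single library left out, counts ran from 0 to 7798 for lenvatinib against parental, 0 to 5819 for resistant against parental, 0 to 6286 for resistant against lenvatinib and 0 to 567 for line SNU-6625 against line SNU-6624; the lone library of a group is then assumed to vary like the others. Lists called by camera were 16, 14, 14 and 13, and 0 for each comparison with an estimated correlation and 0 with fry. With a library left out they ran from 13 to 18, 5 to 16, 13 to 17 and 5 to 14. The covariance of lenvatinib and resistant changes was 1.11, and 1.03 with no replicate block, 1.01 with DESeq2 and 0.417 with at least 5 CPM in 2 libraries. Not run were the alternatives on the authors' normalized values and on transcripts, since the files used hold counts per gene. Depth limits genes under the floor of 3 counts per library.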

Other observations

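The tests of the lists below were chosen only after the values were seen. Of the intestinal epithelium genes, the microvillus gene Vil1 had 231 ± 115 CPM (SD, n = 4) in parental lines. In the lenvatinib libraries of SNU-6624 and SNU-6625, Cdh17 had 16.7 and 42.9 CPM, and Lgals4 40.2 and 72.2 CPM. Of 17 stomach genes 1 reached 10 CPM in every parental line, and of 16 pancreas genes 0 did. Of 26 stratified squamous genes 9 did.

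Gclc, chosen for mention after its values were seen, encodes the catalytic subunit of the rate-limiting enzyme of glutathione synthesis. It had 5019.9 and 5584 CPM in the lenvatinib libraries, 633 and 648 CPM in the parental libraries and 329 and 2193 CPM in the resistant libraries of SNU-6624 and SNU-6625. Its log2 fold change for lenvatinib against parental was 3.03 (SE 0.81) and was not called (edgeR adjusted p = 0.0931).

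Stratified squamous genes may be higher in resistant than in lenvatinib-treated organoids, mostly through lower levels under lenvatinib. Without the members whose values had been seen, 13 tested genes gave p = 0.000122 by camera with the preset correlation and p = 0.302 with an estimated correlation, which leaves the hypothesis open. Their median log2 fold change was -2.80 for lenvatinib against parental and 0.53 for resistant against parental. The condition that both hold was set after the first results of this list were seen. Krt16 had 30.9 and 221 CPM in resistant, 1.05 and 0.726 CPM in lenvatinib and 12.1 and 1.13 CPM in parental libraries of SNU-6624 and SNU-6625. Other members of the full list were lower in resistant than in parental SNU-6625. Krt4 had 234 against 1382 CPM, Krt13 4.61 against 21.0 CPM and Trp63 0.298 against 1.47 CPM.

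For the difference between lines, 3 of the 10 splits of the 6 libraries gave as many genes as the real split, which called 2, the real one included, and the highest other split called 898. The 10 splits are too few for a share under 0.05. Of the 4 splits that part the lines in all 3 conditions, the other 3 called 0 genes by edgeR. The 2 splits with 898 genes are a single comparison, since with group in the model both only set resistant SNU-6624 against resistant SNU-6625, 1 library each.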
